A study of Mus musculus with 17 samples.

How the data were processed

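RNA was measured in 17 heart libraries of C57BL/6 mice. The measure was RNA-seq of total RNA. Per the labels, mice were kept in 12 h of light and 12 h of dark on normal chow, hearts were frozen on dry ice, RNA was taken with Trizol, and libraries were made from 1 ug of total RNA with a TruSeq RNA kit. Harvest was at about zeitgeber hour 10, that is 10 hours after lights on. The groups were Control (3 libraries), and transverse aortic constriction (TAC), an operation that narrows the aorta and loads the heart with pressure, at 1 week with vehicle (4) or SR9009 (4) and at 6 weeks with vehicle (3) or SR9009 (3). SR9009 is an agonist of the nuclear receptors REV-ERB alpha and beta, repressors in the circadian clock. The labels do not say whether Control mice had sham surgery or a vehicle, give no sex, and do not state that replicates are separate animals, so p-values measure only the spread between these samples, which may be technical. For Control no week is given, and no Control group was matched to each time. Comparisons with Control or between both times therefore cannot separate TAC or time under load from age, length of dosing or batch.

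The authors deposited 1 table per library with 41126 genes and 4 measurement columns, in the layout of a Cuffdiff read-group table, per the file headers. The first column holds raw fragments per gene, estimated counts that are not normalized by the authors: 2289 to 2678 values per library were not whole numbers. The pair of scaled columns deposited beside it are identical and equal the raw fragments times 1 factor per library, so they were not used. The last deposited column is FPKM, made by the authors, which was not used for tests because effective lengths were left blank and its ratio to the scaled fragments was not the same in every library. The genome build was mm10, per the submitters' processing notes. The aligner, the counter's version and the annotation are not given in the sources used here. Of the gene IDs, 40252 were found in a GENCODE annotation of the mm10 assembly, which gave symbols, gene types and coordinates, and 874 were not, which held 0.776% to 2.357% of a library's fragments. The kit as named in the labels does not mark strand and no counting by strand is stated, so overlapping genes on opposite strands, near-identical paralogs such as histone genes, and repeated small RNA genes are uncertain.

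Genes that the authors' tool marked as holding too many fragments to be counted (status HIDATA) were written as 0 fragments, and the status was set per group. It applied to 78 genes, 20 of them in every library, Myh6 and Ttn among these, and 58 in some groups only. All 78 were left out, because their zeros are not measurements. Of the 58, 27 had a mean of 50 or more fragments where counted. Most lie in 1 stretch of chromosome 7, from 130162451 to 133123350, the span of the Fgfr2 gene model, counted only in Control and TAC 1 week vehicle. Malat1 was uncounted only in TAC 1 week SR9009. Of the 37 genes of the mitochondrial genome, 7 had a fragment in any library, so mitochondrial transcripts are not reported, except for mt-Ts1, which the naming rule took. The 18 genes with status FAIL carry fragment values and were kept.

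The estimated counts were rounded to whole numbers and fitted with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with TMM scaling and the filterByExpr count filter, in 1 model of all 17 libraries with a mean per group. The filter removed 25117 genes and left 15931. The common dispersion was 0.0106, a biological coefficient of variation of 0.103, with 12 residual degrees of freedom. Adjusted p-values are edgeR's after Benjamini-Hochberg adjustment within each comparison, two-sided, with a threshold of 0.05 and no minimum fold change. Expression is given as CPM, counts scaled to a common library total, and errors of log2 fold changes are standard errors. Library totals ran from 8.68 to 15.81 M (mega) fragments. Values near 1 CPM therefore rest on few fragments per library and carry a large counting error.

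The gene lists (14 pathways and functions, 15 sets of cell type markers) and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, up to 8 rises and 8 falls with the largest log2 fold change among genes that passed, had a mean of at least 5 CPM in a group, and did not overlap between the groups' libraries, leaving out predicted genes. It added the 2 members of each list with the smallest p and a fixed set of 16 heart and clock genes. Where no gene passed, the 5 with the smallest p were named. Other genes named in the text were chosen after their values were seen. These are Cenpf at 1 week, members named to spell out a short count (Upk1b, Wt1, Mmp9, Col3a1, Col5a1, Serpinh1 and the like), Myl7, Ddx3y, the globin genes and the small RNA genes. The values of some list members are not reported here. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and its preset correlation of 0.01 between genes, adjusted over all lists and comparisons, and again with an estimated correlation. The pathway lists are hypertrophy and fetal genes, adult contractile and ion handling genes, extracellular matrix and fibrosis, fatty acid oxidation, oxidative phosphorylation, glucose use and glycolysis, branched-chain amino acid breakdown, circadian clock, REV-ERB repressed genes, inflammation and chemokines, cell cycle, unfolded protein response, autophagy and mitophagy, and immediate early genes. Of the marker lists, that for lung and liver had no measured member.

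The steps were tested on simulated data with 200 genes changed by known amounts. Of genes changed 2-fold, 92.5% were recovered for TAC 1 week vehicle against Control, 97% for TAC 6 week vehicle against Control, 98.5% for SR9009 against vehicle at 1 week and 91% at 6 weeks, and 86.6% for the difference between both SR9009 effects. Of genes changed 1.5-fold, 73.1%, 67.2%, 74.6%, 70.1% and 37.3% were recovered. The changed genes had a mean of at least 5 CPM, and each gene was drawn independently with the same spread in all groups. Whole libraries that stand apart from their group were not simulated, so these rates may overstate what the real comparisons could find. Replicates were checked for copies of 1 library. Over the 21 pairs within groups, the mean chi-square per gene was 2.62 to 35.15, where sampling noise alone gives about 1, so each library was counted as a sample of its own. Groups share some replicate numbers, which were not treated as pairs. Alternatives fixed beforehand were RLE scaling, no count filter and a stricter one, DESeq2 1.42.0, voom with library weights, a fit of the compared groups alone, a 1.5-fold minimum, the replicate number as a block, and each library left out in turn. A covariate for library total, a robust fit, the uncounted genes kept as written, and leaving out Control 2, TAC 1 week SR9009 2 and TAC 6 week vehicle 1 together were added after the data were seen.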

Results

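The study sequenced RNA from mouse hearts harvested at about zeitgeber hour 10, in 5 groups. These were Control (n = 3) and hearts 1 week or 6 weeks after TAC from mice given vehicle (n = 4 and n = 3) or the REV-ERB agonist SR9009 (n = 4 and n = 3) daily. Library totals were 9.678 to 10.14 M fragments in Control, 8.683 to 12.575 M in TAC 1 week vehicle, 10.774 to 13.366 M in TAC 1 week SR9009, 13.35 to 15.81 M in TAC 6 week vehicle and 9.908 to 13.646 M in TAC 6 week SR9009. Depth therefore differed between groups, with larger totals in each TAC 6 week vehicle library than in any Control library. The first principal component held 45.8% of the variance of the 1000 most variable genes and set the 3 Control libraries apart from the 1-week TAC libraries.

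The first comparison asked how hearts of vehicle-treated mice 1 week after TAC differed from Control. The genes of the stressed ventricle stood far above Control. Acta1 (ENSMUSG00000031972.4, chromosome 8, 123891769 to 123894751), the skeletal actin of fetal and overloaded heart muscle, was at 1590 ± 558 CPM (SD, n = 4) against 130 ± 34.4 CPM (SD, n = 3), a log2 fold change of 3.60 ± 0.37 (adjusted p = 9.95e-05). Nppb (ENSMUSG00000029019.8, chromosome 4, 147985788 to 147987205), which encodes the wall-stress hormone BNP, was at 513 ± 108 against 110 ± 6.69 CPM, a log2 fold change of 2.23 ± 0.17 (adjusted p = 3.37e-06). Nppa, the gene of the atrial hormone ANP, rose by 2.57 ± 0.51. Of the 13 hypertrophy and fetal genes 11 rose and 0 fell, 11 also when adjusted over the list alone. The slow myosin gene Myh7, at a log2 fold change of 0.78 ± 0.41 (adjusted p = 0.205), did not pass.

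Genes of connective tissue and of cell division rose at 1 week. In all, 27 of 33 extracellular matrix genes rose and 0 fell, 28 when adjusted over the list alone. Postn (ENSMUSG00000027750.11, chromosome 3, 54361109 to 54391037), secreted by activated fibroblasts, went from 70.9 ± 3.34 CPM (SD, n = 3) to 618 ± 295 CPM (SD, n = 4), a log2 fold change of 3.13 ± 0.60 (adjusted p = 0.00368). Cilp, a matrix protein that binds growth factors, rose by 2.74 ± 0.43, elastin (Eln) by 1.53 ± 0.26, tenascin C (Tnc) by 3.38 ± 0.77 and Col1a1, a chain of type I collagen, by 1.61 ± 0.34. Of 28 cell cycle genes 26 rose, 27 when adjusted over the list alone, among them the proliferation marker Mki67 by 2.89 ± 0.40 and the mitotic transcription factor Foxm1 by 3.16 ± 0.44. The list's 1 fall was the kinetochore gene Cenpf, at -0.48. Among genes that met the naming rule, the largest log2 fold changes were those of the histone genes Hist1h2bj (4.20 ± 0.54) and Hist1h3c (4.05 ± 0.60), although near-identical histone genes can share reads. Macrophage markers rose in 8 of 8 cases, in 8 of 8 when adjusted over the list alone. Of 22 inflammation genes 6 rose, 13 when adjusted over the list alone, with the endotoxin receptor Tlr4 at 0.59 ± 0.12 and the chemokine Ccl8 at 2.19 ± 0.48. Of 12 immediate early genes 4 rose, 6 when adjusted over the list alone, Jun by 0.69 ± 0.09 and Junb by 0.82 ± 0.20.

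Among lists of fuel use, those for fatty acid oxidation, oxidative phosphorylation and branched-chain amino acids held falls and no rises at 1 week, and that for glucose use held both. Of 25 fatty acid oxidation genes 6 fell and 0 rose, 14 when adjusted over the list alone. Ucp3, an inner-membrane carrier induced by fatty acids, fell by 1.28 on the log2 scale, from 79.8 ± 12.1 to 33.1 ± 9.67 CPM, and the enoyl-CoA hydratase gene Echs1 by 0.33. Of 28 oxidative phosphorylation genes 4 fell, 4 when adjusted over the list alone, including the cytochrome oxidase subunits Cox7a1 (-0.58 ± 0.16) and Cox8b (-0.41 ± 0.12). Of 14 genes of branched-chain amino acid breakdown 8 fell, 9 when adjusted over the list alone, with Bckdha, a subunit of the rate-limiting dehydrogenase, at -0.73 ± 0.15 and Ppm1k, the phosphatase that activates it, at -0.80 ± 0.19. Glucose use was mixed, with 5 rises (Gapdh 0.26 ± 0.05) and 3 falls (Pfkfb1 -1.42 ± 0.32) among 21 genes, 6 and 5 when adjusted over the list alone. Among 17 adult contractile and ion handling genes 3 rose and 5 fell, 5 and 8 when adjusted over the list alone: the potassium channel genes Kcnj2 (-0.70 ± 0.15) and Kcnd2 (-0.67 ± 0.14) and the calcium pump gene Atp2a2 (-0.44 ± 0.13) were lower. The mitophagy kinase Pink1 (-0.84 ± 0.15) and receptor Fundc1 (-0.30 ± 0.10) were the 2 of 18 autophagy genes that fell, 1 when adjusted over the list alone. In the unfolded protein response list Hspa5 fell by 0.43, Atf4 rose by 0.38, and 1 further gene of 17 fell; 3 rose and 3 fell when adjusted over the list alone. Other large falls at 1 week were Retnla (-3.16 ± 0.43), a marker of alternatively activated macrophages, the retinoic acid hydroxylase Cyp26b1 (-2.13 ± 0.44) and the channel subunit Cngb3 (-1.88 ± 0.31). Of 19 clock genes 3 fell, 3 when adjusted over the list alone: Hlf (-0.88 ± 0.26), Cry2 (-0.60 ± 0.18) and Nr1d1 (-0.51 ± 0.16), the gene of REV-ERB alpha. None of the 9 measured REV-ERB repressed genes passed (0 adjusted over the list alone; Ccl2 1.23 ± 0.42, adjusted p = 0.0592), nor did Pdk4 (-0.86 ± 0.30, adjusted p = 0.0575).

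Over all genes, edgeR's quasi-likelihood test called 2362 of 15931 at 1 week, 1419 higher and 943 lower than in Control. Camera gave adjusted p = 9.22e-21 for the cell cycle list, 9.63e-16 for matrix, 9.24e-09 for hypertrophy, 2.6e-06 for macrophages, 1.72e-05 for inflammation and 0.00107 for immediate early genes, all upward, and 8.05e-06 for fatty acid oxidation, 5.35e-04 for branched-chain amino acids and 0.00107 for oxidative phosphorylation, all downward. With an estimated correlation the adjusted p of these 9 lists lay between 0.693 and 0.893, so none of these calls held. For the cell cycle list, with 26 of 28 members up, that correlation was 0.789 and camera's unadjusted p was 0.0374. At such correlations camera can miss a list whose members moved together, so a lost call does not show that a list was unchanged. The lists of glycolysis (0.73), clock (0.169), REV-ERB repressed (0.255), unfolded protein response (0.716), autophagy (0.305) and contractile genes (0.334) were not called. The count fell to 1026 without Control 1, 1291 without Control 2, 1074 without Control 3, 1383 without TAC 1 week vehicle 3 and 993 without TAC 1 week vehicle 4. Of the genes named above, Echs1, Cox7a1, Cox8b, Cry2, Hlf, Nr1d1, Atp2a2 and Fundc1 each lost their call in 4 or more of the 7 leave-outs, and Junb lost it without Control 2 or TAC 1 week vehicle 4. Without Control 2, TAC 1 week SR9009 2 and TAC 6 week vehicle 1 together camera called the clock downward (0.0029) and REV-ERB repressed genes upward (0.0417).

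**Figure D1:**
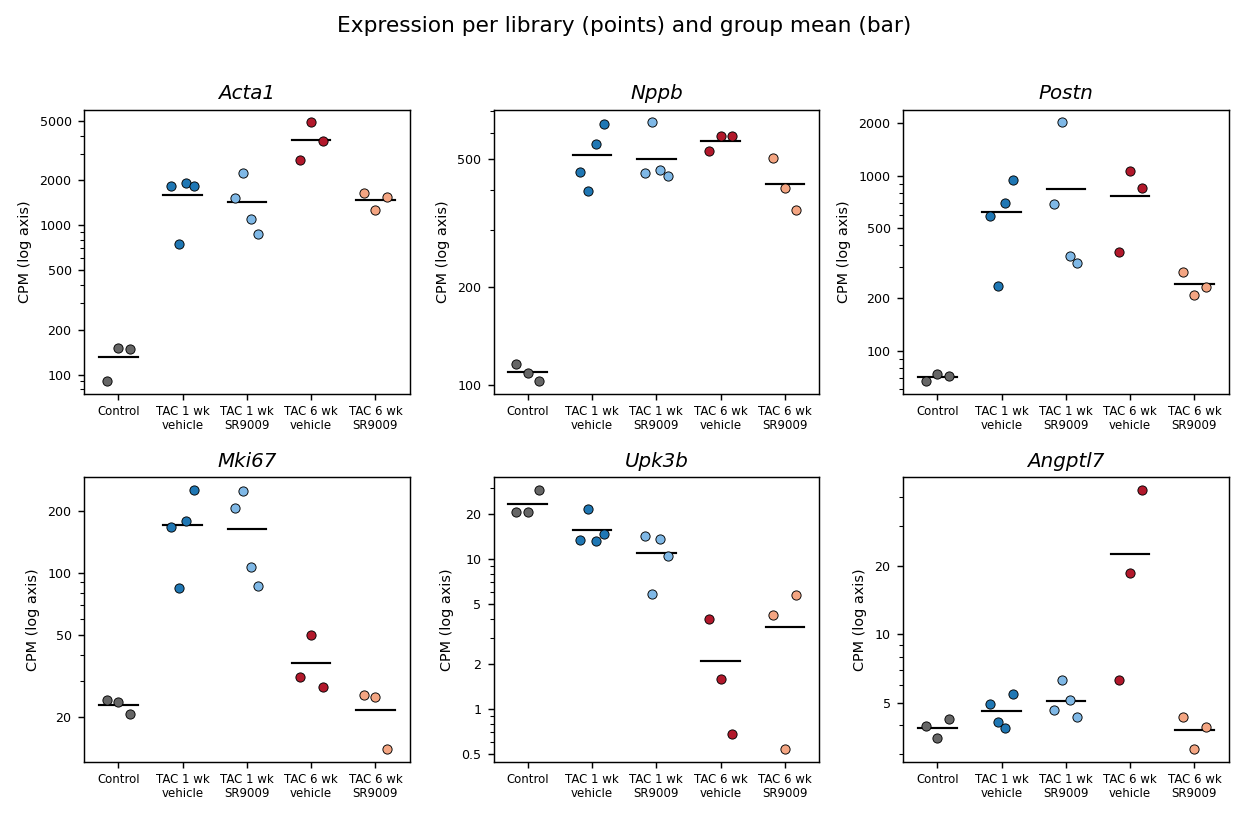
Expression of 6 genes in CPM (log axis) by group, with a point per library (replicates in order from left to right) and a bar at the group mean. Acta1 went from a mean of 130 CPM in Control to 1590 and 3760 CPM in the vehicle groups, Mki67 was high only in the 1-week groups among those plotted, and Angptl7 was above 10 CPM only in TAC 6 week vehicle 2 and 3.

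The second comparison asked how hearts of vehicle-treated mice 6 weeks after TAC differed from Control. All 13 hypertrophy and fetal genes rose (13 when adjusted over the list alone). Acta1 reached 3760 ± 1090 CPM (SD, n = 3) against 130 ± 34.4 CPM (SD, n = 3) in Control, a log2 fold change of 4.85 ± 0.40 (adjusted p = 9.21e-07). Nppa rose by 3.23 ± 0.54, Myh7 by 2.38 ± 0.45 and Nppb by 2.37 ± 0.18. Of 33 matrix genes 17 rose and 0 fell, 24 when adjusted over the list alone. Among them were the thrombospondins Thbs4 (4.40 ± 0.81) and Comp (3.98 ± 0.56), the collagen gene Col12a1 (3.77 ± 0.81), Cilp (3.72 ± 0.45), Postn (3.43 ± 0.63) and the latent TGF-beta binding protein Ltbp2 (3.41 ± 0.60). Ccn2, a matricellular growth factor, rose by 2.22 ± 0.44, while Col1a1 (0.73 ± 0.35, adjusted p = 0.155) did not pass. Dio2, which activates thyroid hormone, rose by 3.30 ± 0.57. Markers of mesothelium, the layer of cells that covers the heart, fell. Upk3b (ENSMUSG00000042985.6, chromosome 5, 136038496 to 136046487) went from 23.3 ± 4.73 to 2.08 ± 1.70 CPM (-3.49 ± 0.50, adjusted p = 1.96e-04). With Msln (-2.46) and Upk1b (-3.51), 3 of 4 measured markers fell (3 when adjusted over the list alone), while Wt1, a transcription factor of the epicardium, was at 10.5 ± 2.55 against 11.1 ± 0.636 CPM (-0.08 ± 0.18, adjusted p = 0.806). The endocytic receptor Lrp2 (-3.55 ± 0.46), Lrrn4 (-3.22 ± 0.45) and the water channel Aqp4 (-2.95 ± 0.22) were other large falls. In each group of 6 weeks Lrp2 and Lrrn4 ranked the libraries as Upk3b did, so they need not be falls separate from it.

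Of 22 inflammation genes 8 rose, 9 when adjusted over the list alone, with Tlr4 at 1.09 ± 0.13 and the prostaglandin synthase Ptgs2 at 3.21 ± 0.66, and 6 of 8 macrophage markers and 2 of 5 fibroblast markers rose (6 and 3 when adjusted over the list alone). Of 25 fatty acid oxidation genes 4 fell and 1 rose, 4 and 1 when adjusted over the list alone: Ucp3 fell by 1.25, and Ppargc1a, the coactivator of mitochondrial genes, rose by 1.15 ± 0.30 (360 ± 195 against 162 ± 4.75 CPM). Among 17 adult contractile and ion handling genes 4 rose and 7 fell, 4 and 9 when adjusted over the list alone, with the calcium buffer Casq2 at 0.42 ± 0.07 and Kcnd2 at -1.03 ± 0.16. Glucose use gave 7 rises (Pgam2 0.43 ± 0.07) and 1 fall (Pfkfb1 -1.98 ± 0.35), 7 and 1 when adjusted over the list alone, and branched-chain amino acid breakdown 2 falls (Bcat2 -0.38 ± 0.08) and 1 rise (Hibch 0.31 ± 0.07), 7 and 1 when adjusted over the list alone. Of 19 clock genes Nfil3 (1.26 ± 0.12) and Cry1 (0.88 ± 0.13), both known to be repressed by REV-ERB, rose and Nr1d1 (ENSMUSG00000020889.11, chromosome 11, 98767932 to 98775333) fell by 0.96, from 61.1 ± 4.87 to 31.4 ± 6.45 CPM (2 up and 1 down when adjusted over the list alone). Of 9 REV-ERB repressed genes 3 rose, Nfil3 and Cry1 among them, and Mmp9 (-1.67) fell, 3 and 1 when adjusted over the list alone. In the cell cycle list only Cenpf passed, at -1.79 ± 0.17 (1 when adjusted over the list alone), and in the oxidative phosphorylation list only Cox8b, at -0.42 ± 0.13 (0 when adjusted over the list alone). Autophagy gave 4 rises (Lamp1 0.36 ± 0.06, Bnip3 0.54 ± 0.10) and 2 falls, 5 and 3 when adjusted over the list alone. The unfolded protein response gave 2 rises (Atf4 0.58 ± 0.10) and 1 fall (Hspa5 -0.31 ± 0.08), and immediate early genes 3 rises, the same numbers when adjusted over the list alone.

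At 6 weeks edgeR called 3292 genes, 1705 higher and 1587 lower. Camera gave adjusted p = 2.44e-13 for hypertrophy, 4.21e-11 for matrix, 1.49e-04 for inflammation, 3.34e-04 for macrophages and 0.0489 for fibroblasts, upward, and 0.00463 for mesothelium and 0.00956 for fatty acid oxidation, downward; with an estimated correlation these 7 had adjusted p = 0.693 to 0.913. Contractile genes (0.224), glycolysis (0.16), branched-chain amino acids (0.126), clock (0.98), REV-ERB repressed genes (0.169), oxidative phosphorylation (0.081), cell cycle (0.345), unfolded protein response (0.824), autophagy (0.305) and immediate early genes (0.126) were not called. The fibroblast call was lost without Control 1 (0.0742), Control 3 (0.0623), TAC 6 week vehicle 1 (0.124) or TAC 6 week vehicle 3 (0.0664). It was also lost with the replicate number as a block (0.0626). The count of genes was 1981 without Control 1, 2099 without Control 3, 1878 without TAC 6 week vehicle 2 and 1991 without TAC 6 week vehicle 3, and 241 with library total as a covariate, which also took fatty acid oxidation to adjusted p = 0.258 and fibroblasts to 0.25. In that fit the standard errors were 1.43 times as large at the median, and 99.8% of the 3292 genes kept their sign. Ppargc1a and Atp2a2 (-0.51 ± 0.14) lost their call without TAC 6 week vehicle 2 or 3, Hspa5 without Control 2 or TAC 6 week vehicle 2, and Cox8b in 5 of 6 leave-outs. Without TAC 6 week vehicle 1 camera called oxidative phosphorylation downward (0.0358) and immediate early genes upward (0.0233), and without TAC 6 week vehicle 3 REV-ERB repressed genes upward (0.0332). Leaving out Control 2, TAC 1 week SR9009 2 and TAC 6 week vehicle 1 together gave a downward call of oxidative phosphorylation (0.00802) and ended that of fibroblasts (0.0837).

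The vehicle libraries of 6 weeks were not alike. Arntl (ENSMUSG00000055116.7, chromosome 7, 113207465 to 113314126), which encodes the clock activator BMAL1, was at 42.8 CPM in TAC 6 week vehicle 1 and at 3.6 and 2.7 CPM in vehicle 2 and 3. Per2 (ENSMUSG00000055866.9, chromosome 1, 91415982 to 91459324), a repressor of that activator, was at 2.3, 58.9 and 67.2 CPM in the same order, and Myh7 at 561, 2760 and 3010 CPM. The group means of Arntl (0.55 ± 0.66, adjusted p = 0.601), Per2 (0.77 ± 0.57, adjusted p = 0.365), Dbp (-0.65 ± 0.34, adjusted p = 0.193) and Npas2 (0.54 ± 0.30, adjusted p = 0.212) did not differ from Control in the test. Without TAC 6 week vehicle 1, Arntl turned to -1.83 and passed, as did Per2, and without TAC 6 week vehicle 3 Npas2 passed.

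The effects of TAC at both times had a correlation of 0.667 across genes, which are not independent replicates. Unchanged groups against the same Control libraries gave 0.558 in simulation. The covariance was 0.162 against 0.032 in the simulation. Of the genes called at each time, 537 rose at both and 533 fell at both, where independent lists would share 152 and 94, and 4 went opposite ways; part of the excess may come from the shared Control libraries, which are too few to split.

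The third comparison asked how hearts of vehicle-treated mice 6 weeks after TAC differed from those at 1 week. Age, length of dosing and batch may differ between these groups too. All 28 cell cycle genes were lower at 6 weeks than at 1 week (28 when adjusted over the list alone), for example the checkpoint kinase Bub1 (-2.86 ± 0.47) and the survivin gene Birc5 (-2.10 ± 0.31). The histone gene Hist1h2bk, which has near-identical copies, was lower too (-2.82 ± 0.53). Of 13 hypertrophy genes 6 were higher, 7 when adjusted over the list alone, including Myh7 (1.60 ± 0.40), Acta1 (1.24 ± 0.31), the intercalated disc gene Xirp2 (1.01 ± 0.20) and the Z-disc gene Csrp3 (0.35 ± 0.07). Among 33 matrix genes Comp was higher (2.89 ± 0.45) and Eln (-1.31 ± 0.25), Col3a1, Col5a1 and Serpinh1 were lower, the same 1 and 4 when adjusted over the list alone. Mesothelial markers were lower in 3 of 4 cases (3 when adjusted over the list alone), Upk3b at -2.92 ± 0.49. Autophagy genes were higher in 5 of 18 cases, 7 when adjusted over the list alone, with Bnip3 at 0.64 ± 0.09 and Gabarapl1 at 0.42 ± 0.10. Of 19 clock genes 3 were higher, among them Nfil3 (1.10 ± 0.11) and Cry1 (0.84 ± 0.12), 3 when adjusted over the list alone. Jun was lower (-0.64 ± 0.09), and Ppargc1a (1.39 ± 0.28), Angptl7 (2.28 ± 0.40), an angiopoietin-like factor, the transcription factor Tbx15 (1.97 ± 0.28), the water channel Aqp8 (1.53 ± 0.16) and endothelin 3 (Edn3, 1.32 ± 0.19) were higher.

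In all, 985 genes were higher and 940 lower at 6 weeks than at 1 week, 1925 together. Camera called cell cycle (adjusted p = 1.36e-21) and mesothelium (0.00107) downward and hypertrophy (3.3e-05) and autophagy (0.00242) upward; with an estimated correlation these had adjusted p = 0.693 to 0.79. Camera did not call the lists of matrix (0.73), clock (0.126), REV-ERB repressed genes (0.652), glycolysis (0.141), contractile genes (0.821), fatty acid oxidation (0.224), oxidative phosphorylation (0.339), branched-chain amino acids (0.119), inflammation (0.843), unfolded protein response (0.403) or immediate early genes (0.202). Among 21 glycolysis genes 3 were higher (3 when adjusted over the list alone), with Hk2 at 0.33 ± 0.07 and Pfkfb2 at 0.54 ± 0.13. Among 17 contractile genes 2 were lower, the potassium channel Kcnq1 (-0.43 ± 0.09) and the gap junction gene Gja1 (-0.38 ± 0.11), and 1 was higher and 2 lower when adjusted over the list alone. Of 9 REV-ERB repressed genes 2 were higher, and 3 higher and 1 lower when adjusted over the list alone. Inflammation had 1 higher gene (Tlr4, 0.51 ± 0.12) and the unfolded protein response 2, the same when adjusted over each list alone, and 0 of 28 oxidative phosphorylation and 0 of 14 branched-chain amino acid genes passed either way. Without TAC 6 week vehicle 1 camera called the clock upward (5.64e-05) and endothelial markers downward (0.00188). Without TAC 1 week vehicle 2 it called fatty acid oxidation (0.0306), oxidative phosphorylation (0.0445) and branched-chain amino acids (0.0108) upward. Without TAC 6 week vehicle 2 it called oxidative phosphorylation (0.0465) and branched-chain amino acids (0.021) upward and immediate early genes (0.0465) downward. The count was 1238 without TAC 1 week vehicle 1, 1271 without TAC 1 week vehicle 3, 1114 without TAC 6 week vehicle 2, and 751 without TAC 6 week vehicle 3. It was 3343 without Control 2, TAC 1 week SR9009 2 and TAC 6 week vehicle 1 together and 94 with library total as a covariate. In that fit standard errors were 1.52 times as large at the median, 99.6% of the 1925 genes kept their sign, and the hypertrophy list was at adjusted p = 0.0563. It also called matrix downward (0.00565) and fatty acid oxidation (0.00918) and branched-chain amino acids (0.0298) upward. Without the 3 libraries together camera called the clock upward (6.23e-05) and endothelial markers downward (0.00222). Of the 3, only TAC 6 week vehicle 1 is in this comparison. Myh7, Acta1, Pfkfb2 and Tlr4 lost their call without TAC 6 week vehicle 2 or 3, as did Gja1, also without TAC 1 week vehicle 2 or 3. Hk2 and Gabarapl1 lost it without TAC 6 week vehicle 3.

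**Figure D2:**
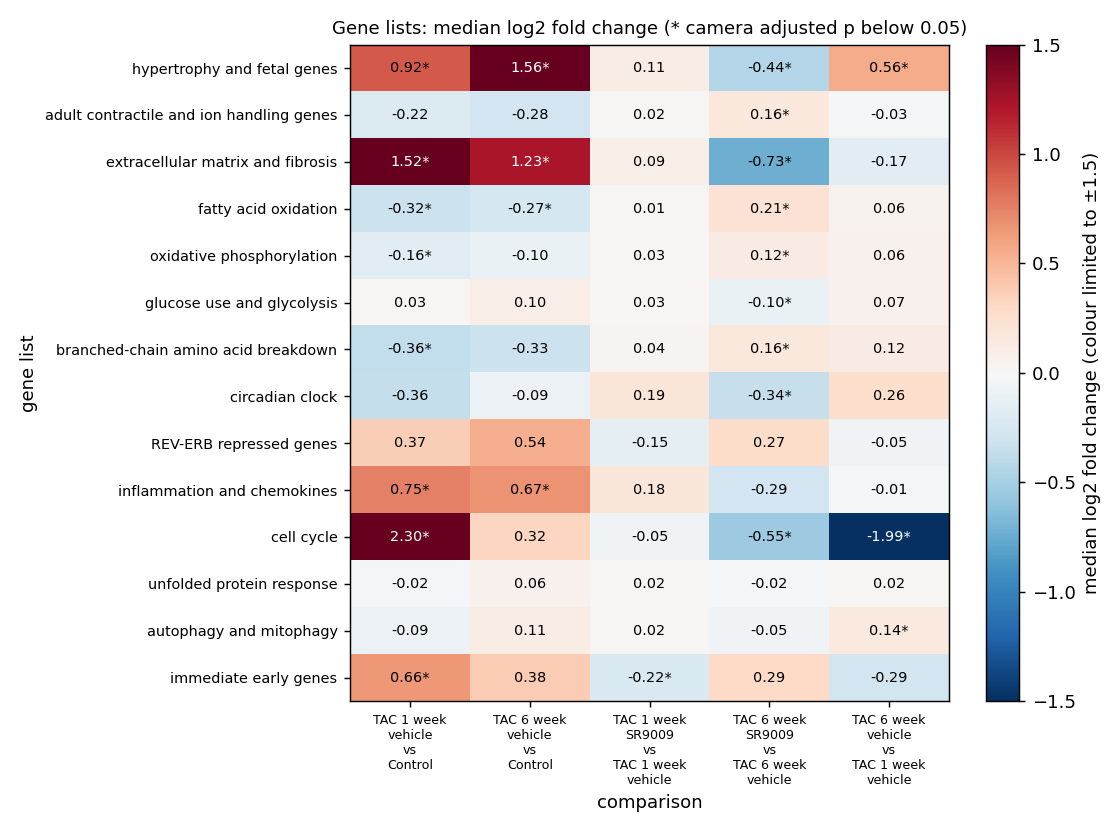
Median log2 fold change of 14 gene lists (vertical) in 5 comparisons (horizontal); the colour shows the median and an asterisk an adjusted p under 0.05 in camera with its preset correlation. Matrix and hypertrophy lists were higher in TAC vehicle than in Control at both times (matrix medians 1.52 and 1.23) and lower with SR9009 than with vehicle at 6 weeks (-0.73 for matrix); no call held with an estimated correlation.

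The fourth comparison asked what SR9009 did at 1 week. No gene passed in edgeR's quasi-likelihood test, 0 of 15931, with 1019 at an unadjusted p under 0.05, where chance gives 797; DESeq2 called 13 and voom with library weights 1. The 5 genes with the smallest p, each at adjusted p = 0.269, were A230004M16Rik (-0.46 ± 0.08), the mitochondrial serine tRNA mt-Ts1 (0.56 ± 0.10; few mitochondrial genes were counted), the RNA of RNase MRP Rmrp (-1.07 ± 0.20), the prostaglandin D synthase Ptgds (0.46 ± 0.09) and the synaptic scaffold gene Shank3 (-0.43 ± 0.08). Fetal and matrix genes did not pass. Acta1 was at 1440 ± 608 CPM with SR9009 (SD, n = 4) and 1590 ± 558 CPM with vehicle (SD, n = 4). Nppb was at 501 ± 98.1 and 513 ± 108 CPM, and Postn at 842 ± 800 and 618 ± 295 CPM. Among genes that REV-ERB represses, Npas2 was at 3.41 ± 0.698 CPM with SR9009 and 5.95 ± 0.686 CPM with vehicle (-0.80 ± 0.27, adjusted p = 0.626). Arntl was at 9.54 ± 2.37 and 17.4 ± 3.72 CPM (-0.86 ± 0.58, adjusted p = 0.849). Per2 was at 33.3 ± 2.19 and 18.6 ± 4.83 CPM (0.83 ± 0.51, adjusted p = 0.825), Nr1d1 at 41.1 ± 4.28 and 43.1 ± 5.42 CPM, and Cry1 at 11.1 ± 0.921 and 8.72 ± 0.748 CPM (0.34 ± 0.12, adjusted p = 0.654). Of 19 clock genes 6 had each SR9009 library above each vehicle library, Per2 and Cry1 among them, and 2 had each below, Npas2 and Arntl. Of 9 REV-ERB repressed genes 1 (Cry1) lay above and 2 below. Over all genes 4.35% did not overlap, against 2.86% by chance.

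Camera called 2 lists at 1 week. Immediate early genes were called downward with SR9009 (adjusted p = 0.0046, and 0.79 with an estimated correlation): 0 of 12 passed over all genes and 2 when adjusted over the list alone, the phosphatase gene Dusp1 (-0.31 ± 0.07) and Jun (-0.28 ± 0.08). Smooth muscle and pericyte markers were called upward (0.00818, and 0.693 with an estimated correlation), with 0 of 6 members past the threshold (0 adjusted over the list alone) and all 6 above 0. The first call was lost without TAC 1 week vehicle 4 (0.0504) or TAC 1 week SR9009 3 (0.0706), and the second without TAC 1 week vehicle 4 (0.0626) or TAC 1 week SR9009 2 (0.11). Of 9 REV-ERB repressed genes 2 were lower, Npas2 and Mmp9 (-1.43 ± 0.49), and 1 higher, Cry1, when adjusted over the list alone (camera 0.255). No member of the lists for hypertrophy (0.419), matrix (0.975), fatty acid oxidation (0.656), oxidative phosphorylation (0.827), glycolysis (0.345), branched-chain amino acids (0.701), clock (0.0781), inflammation (0.31), cell cycle (0.701), unfolded protein response (0.701) or contractile genes (0.701) passed, 0 when adjusted over each list alone. The autophagy list (0.592) had 1 up and 1 down when adjusted over the list alone. Medians of the matrix (0.0933) and fatty acid oxidation lists (0.0138) lay above 0 while camera's direction was down. TAC 1 week SR9009 2 stood apart from the other 3 libraries of its group, with Nppa at 933 CPM against 217 to 329 CPM. Without it camera called matrix (8.66e-06) and cell cycle (0.00471) downward and oxidative phosphorylation (2.23e-06), fatty acid oxidation (7.08e-05), branched-chain amino acids (0.00119) and contractile genes (0.00618) upward, a setting that leaves 3 libraries and 1 gene past the threshold. That library held its group's highest Nppa and Postn values, so leaving it out lowers the SR9009 means of such genes by construction. Without Control 2, TAC 1 week SR9009 2 and TAC 6 week vehicle 1 together the same 6 lists were called the same way (matrix 4.42e-06, cell cycle 0.0121, oxidative phosphorylation 6.45e-06, fatty acid oxidation 4.9e-05, branched-chain amino acids 0.0021, contractile genes 0.007). Of these 3 libraries only TAC 1 week SR9009 2 is in this comparison, so those 6 calls largely repeat the setting before. Without the 3 libraries the clock was also called upward (0.00132) and REV-ERB repressed genes downward (0.0286), and smooth muscle was not called (0.0669). With library total as a covariate camera called matrix downward (0.00489) and contractile genes upward (0.0404). Without TAC 1 week vehicle 2, matrix (0.0199) and cell cycle (3.75e-04) were also called downward. Inflammation was called upward without TAC 1 week vehicle 4 (0.0191) or TAC 1 week SR9009 4 (0.0323), and fatty acid oxidation downward without TAC 1 week SR9009 3 (0.0038) or SR9009 4 (0.0181).

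The fifth comparison asked what SR9009 did at 6 weeks. Matrix and fetal genes had lower means with the drug, although 0 members of either list passed over all genes. Acta1 was at 1490 ± 200 CPM with SR9009 (SD, n = 3) and 3760 ± 1090 CPM with vehicle (SD, n = 3), a log2 fold change of -1.34 ± 0.34 (adjusted p = 0.11). Postn was at 240 ± 36.3 and 762 ± 359 CPM (-1.67 ± 0.58, adjusted p = 0.183), and Cilp at 93.1 ± 14.9 and 287 ± 128 CPM (-1.62 ± 0.39, adjusted p = 0.105). Comp was at 6.21 ± 3.42 and 28.7 ± 21.4 CPM (-2.17 ± 0.46, adjusted p = 0.0734). Camera called 10 lists, of which 0 held with an estimated correlation (adjusted p = 0.783 to 0.907), and 0 members of these lists passed over all genes. Of 33 matrix genes 0 lay above 0 and 13 fell when adjusted over the list alone (camera adjusted p = 1.41e-09, and adjusted p = 0.817 with an estimated correlation). Of 13 hypertrophy genes 0 lay above 0 and 6 fell when adjusted over the list alone (1.36e-04, and 0.817 with an estimated correlation). Macrophage markers were called downward (0.00107, and 0.817 with an estimated correlation), with 4 of 8 down when adjusted over the list alone. So were cell cycle genes (0.0034, and 0.907 with an estimated correlation), with 0 of 28 past the threshold over the list alone and 5 above 0. Oxidative phosphorylation genes lay above 0 in 28 of 28 cases, with 0 past the threshold over the list alone (0.0017, and 0.907 with an estimated correlation), and fatty acid oxidation genes in 23 of 25 (0.0017, and 0.888 with an estimated correlation). The 1 fatty acid oxidation gene past the threshold over its list alone was Ppargc1a, in the other direction (-1.12 ± 0.30). Contractile genes lay above 0 in 16 of 17 cases (0.00168, and 0.817 with an estimated correlation), 2 of them up when adjusted over the list alone, Ryr2 at 0.37 ± 0.11 and Kcnj2 at 0.51 ± 0.16. Cardiomyocyte markers lay above 0 in 5 of 5 cases (median 0.167, camera adjusted p = 0.0977), with 1 up when adjusted over the list alone. The remaining calls were glycolysis downward (0.0289, and 0.783 with an estimated correlation) and branched-chain amino acids upward (0.0388, and 0.893 with an estimated correlation), with 0 members past the threshold over each list alone. The clock was called downward (0.0289, and 0.817 with an estimated correlation), with 4 down when adjusted over the list alone.

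Single genes past the threshold numbered 27 in edgeR, 19 higher and 8 lower. Angptl7 (ENSMUSG00000028989.3, chromosome 4, 148495183 to 148500460, inside the Mtor gene) was at 3.80 ± 0.599 CPM with SR9009 and 22.6 ± 18.6 CPM with vehicle (-2.57 ± 0.45, adjusted p = 0.03). The myelin and membrane gene Pmp22 (-0.81 ± 0.15), the basement membrane collagen Col4a3 (-0.76 ± 0.12), the endotoxin-binding protein Lbp (-0.74 ± 0.14), Ugp2, which makes UDP-glucose for glycogen (-0.43 ± 0.08), Vamp3 (-0.41 ± 0.08) and the chemokine scavenger Ackr4 (-0.37 ± 0.07) also fell. Among rises were the microtubule-severing gene Fign (0.98 ± 0.18), Nav2 (0.58 ± 0.11), Ppp1r10, a regulator of protein phosphatase 1 (0.55 ± 0.10), and Lrrtm2 (0.51 ± 0.08), and Ccdc107 (0.91 ± 0.14), which overlaps Rmrp on chromosome 4 and is therefore uncertain. Small nuclear and nucleolar RNAs made up 13 of the 27 calls, where their 130 tested genes would give 0.22 by chance, among them Snora68 (0.94 ± 0.18), Rnu3a (0.83 ± 0.15) and Scarna6 (0.78 ± 0.13). In TAC 6 week vehicle against Control 50 of the 130 were called down, with a median log2 fold change of -0.71. Such RNAs also varied with library total within groups (r = -0.891, permutation p = 9.3e-04; rho = -0.87, permutation p = 0.0011; over 17 libraries), and r was -0.803 (permutation p = 0.0094) without TAC 1 week vehicle 4 and TAC 6 week SR9009 3, the 2 libraries whose deviations from their group's mean total lay farthest from the median deviation.

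The count of 27 depended on single libraries and settings. It was 1482 without TAC 6 week vehicle 1 (672 up, 810 down), where Acta1, Postn, Cilp and Comp passed. It was 2 without TAC 6 week vehicle 2, 7 without vehicle 3, 2 without TAC 6 week SR9009 1, 3 without SR9009 2 and 47 without SR9009 3. Each of the genes named as passing lost its call without TAC 6 week vehicle 2. DESeq2 called 259, voom with library weights 2063, the fit of both groups alone 0 and that with library total as a covariate 0. In the latter standard errors were 1.16 times as large at the median and fatty acid oxidation (0.0563) and branched-chain amino acids (0.16) lost their calls, while immediate early genes were called upward (0.0412). Oxidative phosphorylation lost its call without TAC 6 week vehicle 2 (0.0843) and cell cycle without TAC 6 week SR9009 3 (0.14). Glycolysis was lost without vehicle 1 (0.0666), vehicle 3 (0.0996), SR9009 1 (0.0558) or SR9009 2 (0.066), branched-chain amino acids without vehicle 1 (0.0526), vehicle 2 (0.233), SR9009 2 (0.106) or SR9009 3 (0.136), and the clock without vehicle 2 (0.165), vehicle 3 (0.314), SR9009 1 (0.123) or SR9009 3 (0.0505). Endothelial markers were called upward without vehicle 1 (0.00441), immediate early genes upward without vehicle 2 (0.015) or SR9009 2 (0.0381), and inflammation downward without vehicle 3 (0.0151) or SR9009 1 (0.0206). Without Control 2, TAC 1 week SR9009 2 and TAC 6 week vehicle 1 together inflammation was called downward (0.0385) and endothelial markers upward (0.00894). Only the last of these libraries is in this comparison. In the fit of all libraries inflammation (0.0514), REV-ERB repressed genes (0.76; 1 up and 2 down when adjusted over the list alone), immediate early genes (0.166; 4 up and 1 down), autophagy (0.359) and the unfolded protein response (0.58; 1 down) were not called.

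**Figure D3:**
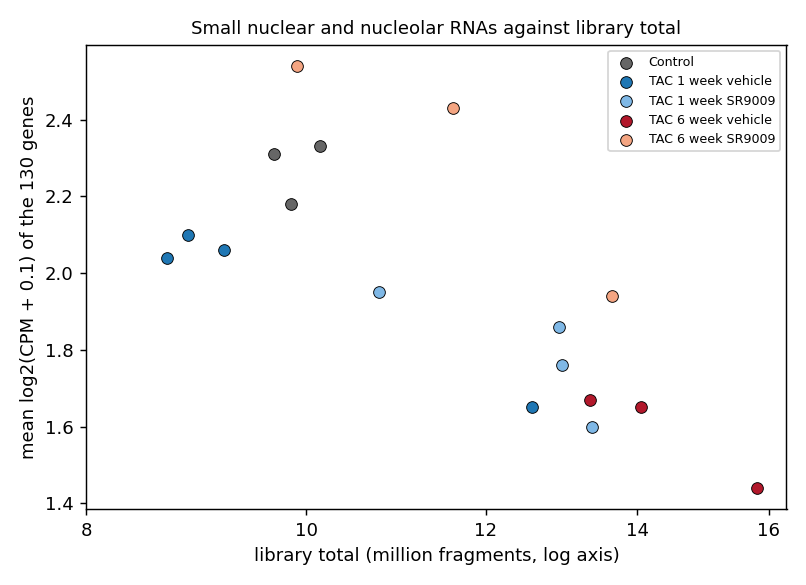
Mean log2(CPM + 0.1) of 130 small nuclear and nucleolar RNA genes (vertical) against library total in M fragments (horizontal, log axis), 1 point per library, coloured by group. The mean was lower in larger libraries, and the 3 TAC 6 week SR9009 libraries (1.94 to 2.54) lay above the 3 TAC 6 week vehicle libraries (1.44 to 1.67).

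Clock genes at 6 weeks had a wide spread among the vehicle libraries, and the SR9009 libraries lay apart from Control. Arntl, which REV-ERB represses, was at 27.5 to 41 CPM with SR9009 and 8.53 to 16.3 CPM in Control. Per2 was at 7.66 to 9.55 and 18.1 to 29 CPM. With SR9009, Arntl was at 33.8 ± 6.82 CPM, Per2 at 8.81 ± 1.00 CPM, Ciart at 3.87 ± 0.256 CPM and Dbp at 14.8 ± 3.98 CPM; with vehicle they were at 16.4 ± 22.9, 42.8 ± 35.3, 13.4 ± 8.26 and 28 ± 17.5 CPM. None passed (Per2 -2.28 ± 0.63, adjusted p = 0.117; Ciart -1.78 ± 0.43, adjusted p = 0.104), and without TAC 6 week vehicle 1 all 4 did, where the clock list was at adjusted p = 2.47e-06 in camera. The receptor gene Nr1d1 was at 34.4 ± 9.91 and 31.4 ± 6.45 CPM (0.12 ± 0.18, adjusted p = 0.786).

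**Figure D4:**
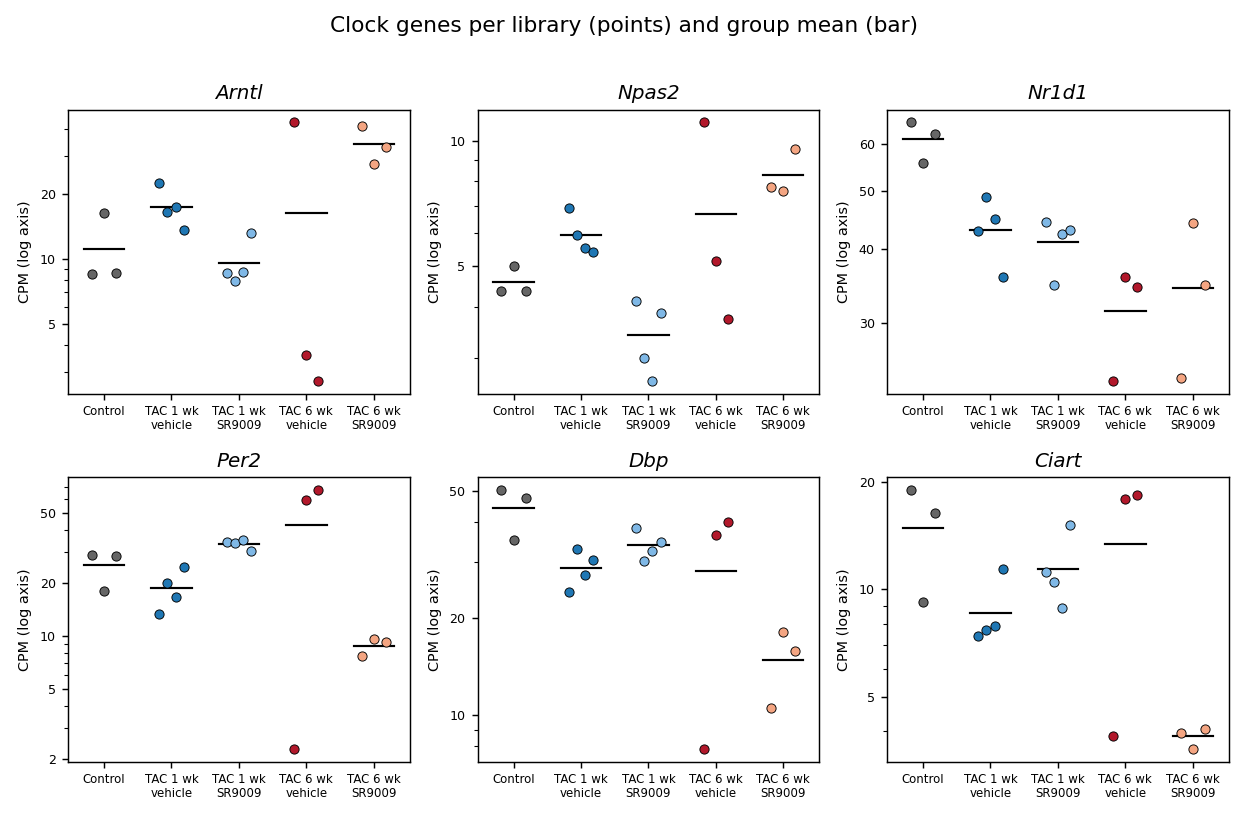
Expression of 6 clock genes in CPM (log axis) by group, with a point per library (replicates in order from left to right) and a bar at the group mean. In TAC 6 week vehicle 1 Arntl was at 42.8 CPM, near the SR9009 libraries of 6 weeks (27.5 to 41 CPM). Per2 was at 2.3 CPM there, below those libraries (7.66 to 9.55 CPM). Both genes were far from vehicle 2 and 3.

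The direction of the SR9009 effect relative to that of TAC was compared across genes. At 6 weeks the correlation of both effects was -0.66, against -0.466 for unchanged groups that share the vehicle libraries in simulation, with a covariance of -0.108 against -0.027. At 1 week the correlation was -0.152 against -0.47, and the covariance -0.0165 against -0.023; with the vehicle libraries split between both effects, the mean correlation over 6 splits was 0.028 (range -0.196 to 0.284). Without TAC 1 week SR9009 4 the 1-week correlation was 0.043. The 3 vehicle libraries of 6 weeks are too few to split, so part of that correlation may come from sharing them. The simulation drew each gene independently with the same spread in all groups. Those vehicle libraries were not alike, so it may understate what sharing them gives. The SR9009 effects at 1 and 6 weeks had a correlation of -0.131 (0.002 in unchanged groups), which was 0.081 without TAC 1 week SR9009 2. The test of the difference between both SR9009 effects called 19 genes, 15 with a higher and 4 with a lower log2 fold change at 6 weeks. The count was 957 without TAC 6 week vehicle 1, 8 without vehicle 2, 9 without vehicle 3, 1 without TAC 6 week SR9009 1, 8 without SR9009 2 and 45 without SR9009 3. It was 8, 10, 7 and 44 without TAC 1 week vehicle 1, 2, 3 and 4, and 10 without TAC 1 week SR9009 3. With library total as a covariate it was 0, with standard errors 1.39 times as large at the median.

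Markers of other cells and tissues gave further values. In TAC 1 week vehicle against Control, camera's adjusted p was 0.398 for cardiomyocytes, 0.975 for atrial muscle, 0.125 for fibroblasts, 0.839 for neutrophils, and 0.511 for T cells. It was 0.975 for B cells, 0.403 for endothelium, 0.897 for smooth muscle, 0.73 for mesothelium, 0.346 for adipocytes, 0.97 for skeletal muscle and 0.843 for red blood cells. The sex-linked genes used as a check of the libraries gave 0.602. The atrial myosin gene Myl7 fell at 6 weeks (-1.90 ± 0.49) from 1.40 ± 0.436 CPM, a level near the floor. Control 2 had lower Y-linked transcripts than Control 1 and 3, with Ddx3y at 72.3 CPM against 212 and 213 CPM. The female marker Xist was at 4.3 CPM in Control 2, against 7.38 and 0.725 CPM in Control 1 and 3, so it was not raised there.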

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

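The counts over other splits of the libraries and the second list of mesothelial genes were planned before their results were seen. The tests of a swap, a wrong label, the time of day, a weaker response, library depth, nuclear RNA and other cell types were chosen only after the patterns were seen.

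In the groups of 4 libraries, a highest or lowest value was set against Dixon's bound for 4 samples for the genes in the text, in 242 group values, library totals included, of which chance alone would put about 12.1 past it; 17 values of genes and 2 totals were. TAC 1 week SR9009 2 held 9 of the genes' values. Nppa was at 933 CPM (217 to 329 CPM in the other 3 libraries), Nppb at 647 (443 to 462), Eln at 75.2 (36.7 to 42.8), Dio2 at 41 (7.24 to 11.8), and Ptgs2 at 18.5 (5.87 to 6.69). Kcnj2 was at 74.6 (93.2 to 96.4) and Cox5a at 218 (282 to 289). The beta globin genes Hbb-bs (1170; 222 to 310) and Hbb-bt (214; 37.7 to 58.8) were high there too, while the alpha globin gene Hba-a1 was at 50.9 CPM (14 to 53.4). In TAC 1 week vehicle 2, Acta1 was at 753 CPM (1830 to 1930) and Bcat2 at 69.4 CPM (56.9 to 58.8). In TAC 1 week vehicle 4, Cenpf was at 103 CPM (66.4 to 72.4), Ccl2 at 7.61 CPM (3.32 to 3.9) and Ciart at 11.4 CPM (7.38 to 7.9). The remaining 3 were Casq2 at 1440 CPM in TAC 1 week vehicle 3 (1370 to 1380), Jun at 92.8 CPM in TAC 1 week SR9009 1 (77.6 to 79.4) and Arntl at 13.1 CPM in TAC 1 week SR9009 4 (7.87 to 8.64). The totals of TAC 1 week vehicle 4 (12.575 M fragments) and TAC 1 week SR9009 1 (10.774 M) also lay apart from their groups.

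The SR9009 effect differed between 1 and 6 weeks in 19 genes by edgeR's test of the difference (adjusted p = 0.00381 to 0.0405). With library total as a covariate 0 genes passed (589 at an unadjusted p under 0.05); standard errors were 1.39 times as large at the median and 100% of the 19 kept their sign. SR9009 libraries were larger than vehicle libraries on average at 1 week and smaller at 6 weeks, and the mean of small RNAs differed by -0.17 and 0.72 at these times, and by 0.17 and 0.42 at equal total. The difference, 6 weeks minus 1 week on the log2 scale, was -0.82 for Ptgds, -0.59 for Vamp3, -0.57 for Ugp2 and -0.53 for Ackr4. It was 0.57 for Dusp1, 0.57 for Lrrtm2, 0.60 for Tshz1, 0.69 for Jun, 0.82 for Nav2 and 0.85 for A230004M16Rik. Among RNAs of the small classes it was 0.99 for Scarna6, 1.03 for Gm24265, 1.06 for Gm24119, 1.14 for Rnu3a, 1.25 for Gm25395, 1.25 for Gm26448, 1.52 for Rnu12 and 2.02 for Rmrp, and it was 1.31 for Ccdc107, which overlaps Rmrp. Jun, for example, was at -0.28 ± 0.08 at 1 week and 0.41 ± 0.09 at 6 weeks.

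Genes counted only in some groups were tested in a fit of Control and TAC 1 week vehicle alone, with 15064 genes. Htra1, a secreted protease, fell (-0.29 ± 0.06), as did Tacc2 (-0.23 ± 0.07), the acyl-CoA dehydrogenase of branched chains Acadsb (-0.44 ± 0.07), Gpr26 (-0.55 ± 0.18) and Pstk (-0.33 ± 0.09), while Cuzd1 (1.34 ± 0.32) and Plekha1 (0.15 ± 0.05) rose. Apart from Acadsb, a member of the list of branched-chain amino acid breakdown, none was on a list.

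Other splits of the same libraries were counted for each comparison. For TAC 1 week vehicle against Control, 2 of 35 splits gave as many genes as the real one (2362; highest other 2529, with TAC 1 week vehicle 2 moved to the side of the Control libraries, which keeps much of the real contrast), so chance could not be excluded by this count. Simulated unchanged groups gave a mean of 0.05 genes here, 0.05 for TAC 6 week vehicle against Control and 0 for SR9009 at 6 weeks over 20 simulations. Each gene was drawn independently, so the simulations hold no structure of the samples. For TAC 6 week vehicle against 1 week, only the real split of 35 did (1925, highest other 685), a share under 0.05. For the difference between both SR9009 effects 3 of 100 did (19, highest other 902). These 100 were the real split and a random draw from a larger number, so their share is itself uncertain. A split with 902 genes also points to a structure of the samples, so chance was not excluded for the 19 genes. For SR9009 at 1 week, with 0 genes, 35 of 35 splits gave as many, and the highest other gave 1401, again a structure of the samples. For TAC 6 week vehicle against Control (3292; highest other 31; 1 of 10) and SR9009 at 6 weeks (27; highest other 79; 3 of 10), the splits are too few for a share under 0.05.

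TAC 6 week vehicle 1 stood apart from vehicle 2 and 3 in clock, fetal and matrix genes. A swap of labels with an SR9009 library of 6 weeks needs a partner out of place, and 0 of the 3 SR9009 libraries correlated better with vehicle 2 and 3 than with each other. For a single wrong label, the mean correlation of this library with the SR9009 libraries exceeded that with vehicle 2 and 3 by 0.34 (-0.03 against -0.37). That difference restates that the library stands apart from vehicle 2 and 3, so it cannot bear out a wrong label. Its small RNA mean (1.65 at 14.05 M fragments) was near that of vehicle 2 (1.67 at 13.35 M). It lay below the SR9009 libraries (1.94 at 13.65 M to 2.54 at 9.91 M), a gap that follows only in part from library total. In it 15 of 17 clock genes lay outside both other vehicle libraries in the direction of their arm of the clock and 40 of 46 fetal and matrix genes below both, but these counts restate the pattern. They bear out neither a harvest at another time of day (or a shifted rhythm) nor a weaker response to the surgery, which stay open with the wrong label, and no biological explanation from the design was tested. Whether this library and the SR9009 libraries of 6 weeks shared a harvest time or rhythm was not tested either. The SR9009 calls made without this library may hold such a difference.

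Small nuclear and nucleolar RNAs were higher in TAC 6 week SR9009 than in vehicle, with a median log2 fold change of 0.79 and 126 of 130 genes above 0, while vehicle lay below Control (median -0.71, 50 called down) and the SR9009 means (1.94 to 2.54) on both sides of Control (2.18 to 2.33). Their mean fell by 0.96 per doubling of library total within groups, but the difference between the groups, 0.72 ± 0.16 (SE), was 0.42 ± 0.09 at equal library total, which argues against depth as the whole cause. A larger share of nuclear RNA might raise other nuclear transcripts alike. The 530 sense intronic and long intergenic genes had a median of 0.11 and an upper quartile of 0.37. How many of them are nuclear was not checked, so these values cannot exclude a larger nuclear share. Of 2 nuclear RNAs, Neat1 was at 2390 to 2550 CPM with SR9009 and 1920 to 2180 CPM with vehicle. Malat1, in a fit of both groups alone, had a log2 fold change of 0.05 ± 0.08. An effect of SR9009 and a difference in library preparation stay open and were not tested. At equal total SR9009 differed from vehicle at 1 week by 0.17 ± 0.08, and TAC 6 week vehicle from Control by -0.17 ± 0.11.

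Mesothelial markers were lower in TAC 6 week vehicle than in Control. A second list of 11 mesothelial genes, 9 of them measured, had a median log2 fold change of -1.97, with 6 called down and 0 up, as fewer mesothelial cells in these samples would give, but Wt1 of the first list went against it (-0.08 ± 0.18). A lower share of every cell type other than cardiomyocytes would lower their markers alike, but the lowest median of the endothelial, fibroblast, macrophage and smooth muscle lists was -0.07. Whether dissection or a loss in the animals lowered them stays open and was not tested, as is so for a biological effect of the surgery. In TAC 6 week SR9009 the marker Upk3b was also low, at 3.51 ± 2.68 CPM (SD, n = 3) against 23.3 ± 4.73 CPM in Control (SD, n = 3).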

How the results depend on the processing

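The covariate for library total, the robust fit, the uncounted genes kept as written and leaving out Control 2, TAC 1 week SR9009 2 and TAC 6 week vehicle 1 together were chosen after the data were seen; all other settings were planned. For counts, no value follows for the planned quantile normalization and pseudocounts of 0.1 and 0.25, meant for normalized values. RLE scaling, the stricter count filter and the robust fit left each count of genes within 1.5 times its value. The causes of the changes below were not tested, except that leaving out libraries or requiring a 1.5-fold change lowers power or adds a criterion by construction. Voom with library weights gave 4677 genes for TAC 1 week vehicle against Control, 5570 for TAC 6 week vehicle against Control, 1 and 2063 for SR9009 at 1 and 6 weeks, 3764 for 6 weeks against 1 week of vehicle and 839 for the difference between both SR9009 effects. DESeq2 gave 13, 259 and 198 for SR9009 at 1 week, at 6 weeks and the difference, and no count filter 4, 242 and 102. On the simulated data with known changes, 25 of 210, 19 of 198 and 19 of 180 DESeq2 calls in these comparisons were not among the changed genes. For edgeR that share was 7.1%, 2.3% and 1.3%. A fit of the compared groups alone gave 3623 for TAC 1 week vehicle against Control, 0 for SR9009 at 6 weeks (edgeR; 2498 at an unadjusted p under 0.05 in the fit of all groups) and 7 for the difference. A minimum of 1.5-fold left 1082, 1310 and 685 for the TAC comparisons at 1 week, at 6 weeks and between both times. Library total as a covariate gave 241 for TAC at 6 weeks, 94 between both times, and 0 for SR9009 at 6 weeks and for the difference. With uncounted genes kept as written SR9009 at 1 week gave 32, and the correlations of SR9009 with TAC effects at 6 weeks and of TAC effects at both times were -0.492 and 0.539; the first was -0.469 without a count filter and the second 0.509 with the covariate. Without the 3 libraries together SR9009 gave 7 genes at 1 week, 2160 at 6 weeks and 1058 for the difference, and the time comparison 3343. The correlation of both SR9009 effects turned to 0.05, and 2 genes turned, Arntl to -1.45 (TAC at 6 weeks) and Dbp to 0.41 (6 weeks against 1 week of vehicle). Whether replicate numbers pair the libraries was not settled. The 31 pairs with the same number had a mean correlation of -0.01 (-0.445 to 0.264, with 1 over 0.1), and that of 84 other pairs was 0.003. However, 9 of 15 libraries numbered 1 to 3 correlated best with their own number. No chance value was computed for that count, and the best matches are not independent of each other. With the replicate number as a block, SR9009 at 6 weeks gave 12 genes and the difference 6, and the other counts stayed within 1.5 times. The block also ended camera's calls of branched-chain amino acids for SR9009 at 6 weeks (adjusted p = 0.061) and of fibroblasts for TAC at 6 weeks (0.0626). Leaving out 1 library gave 993 to 3117 genes for TAC at 1 week, 1878 to 4062 for TAC at 6 weeks, 0 to 3 for SR9009 at 1 week, 2 to 1482 for SR9009 at 6 weeks, 751 to 2628 between both times and 1 to 957 for the difference. It gave correlations of -0.436 to 0.043 for SR9009 and TAC at 1 week and -0.264 to 0.081 for both SR9009 effects, and Arntl at -1.83 to 1.06 for TAC at 6 weeks. The 32 calls of gene lists became 28 to 42 and were 0 with an estimated correlation. With 3 or 4 libraries per group, depth and number limit what can be seen of changes under 1.5-fold. Larger differences of means also did not pass where the libraries of a group differed widely. For SR9009 at 6 weeks Per2 was such a gene, at 2.28, 58.9 and 67.2 CPM in the vehicle libraries.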

Other observations

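The score of the clock's arms was made only after clock genes had been seen, so its tests were chosen after the result. It is the mean log2 CPM of the E-box arm (genes that the BMAL1 complex drives, such as Per2 and Dbp) minus that of the arm that REV-ERB represses (such as Arntl and Npas2). It was 1.82 ± 0.38 in Control (SD, n = 3), 1.15 ± 0.27 in TAC 1 week vehicle (SD, n = 4), 1.73 ± 0.09 in TAC 1 week SR9009 (SD, n = 4), 0.95 ± 1.56 in TAC 6 week vehicle (SD, n = 3) and 0.08 ± 0.39 in TAC 6 week SR9009 (SD, n = 3). Between SR9009 and vehicle it differed by 0.58 at 1 week (two-sided exact permutation p = 0.0286, the smallest possible; adjusted over 4 comparisons 0.0572) and by -0.87 at 6 weeks (exact permutation p = 0.4, smallest possible 0.1). TAC 1 week vehicle differed from Control by -0.67 (exact permutation p = 0.0286, adjusted 0.0572) and TAC 6 week vehicle by -0.87 (exact permutation p = 0.5). None passed after adjustment, but none could, because 0.0572 is the lowest adjusted value that these group sizes allow. Both 1-week differences reached it. By library, the score was -0.85 in TAC 6 week vehicle 1 and -0.34 to 0.45 in TAC 6 week SR9009. It was 1.78 and 1.93 in TAC 6 week vehicle 2 and 3 and 1.39 to 2.08 in Control.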
